A study of Mus musculus with 9 samples.

How the data were processed

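The series holds RNA sequencing of 9 mouse cell libraries, 1 per group. Per the labels, total RNA was extracted with Trizol and libraries were made with the TruSeq RNA kit. The submitters' processing notes name TopHat2 2.0.11, Cufflinks 2.1.2 and Cuffdiff, with no version for the last, and the mouse genome build mm9. The deposited table of the authors gives FPKM per gene (fragments relative to transcript length and to the mapped fragments of the library), with a lower and an upper confidence bound and a status for each value. It has 37975 rows with Ensembl gene identifiers, symbols and loci. Of the rows, 38.9% share their listed locus with another row, so values of overlapping genes are less certain, and the use of strand is not stated. Raw reads were not analysed here.

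No read counts are in the table, so the absolute depth is unknown and no counting interval or detection floor is given. The commonest ratio between low FPKM values was used to estimate the depth of each library relative to wild-type embryonic stem cells (ESC), and only 19.7% to 24.9% of the low values share that ratio. The estimate was 106% for the Sox17 line without doxycycline, 127% at 7 h, 122% at 21 h, 94.8% at 35 h, 98.7% at 49 h, 61.8% at day 6, 63.0% for Sox17-XEN and 67.0% for wild-type XEN. The authors' lower bound was 0 for 98.7% of the values at 1 FPKM or more, so their intervals are wide. Values whose status was not OK were treated as missing. These include the status for too many fragments, given with a listed value of 0 for some of the most abundant genes, which are failed estimates and not absent transcripts.

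Values were used as log2(FPKM + 1). Genes with a maximum of at least 1 FPKM over the libraries were kept (15082 rows). For pairs of single libraries no test exists and no p-value is given. The rule set before the data were examined asked for a difference of at least 2 log2 units and for confidence intervals that do not overlap. Because nearly every interval reaches 0, that rule left at most 9 genes per comparison. The difference of at least 2 log2 units without the interval condition (4-fold in FPKM + 1), listed beforehand as an alternative, is therefore what "higher" and "lower" mean in the counts of genes and of list members, and leading with it was decided after the data were seen. Between the 2 ESC lines without doxycycline, the central 95% of differences ran from -0.90 to 1.01 over 8031 genes with at least 5 FPKM in both. This is a spread over genes between 2 lines and not the error of 1 gene's difference, and it leaves out genes at lower levels. Over all genes compared, 89 were past 2 log2 units between these lines.

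Tests over several libraries, without replicates of any group, were made with limma 3.58.1 in R 4.3.3. They used log2(FPKM + 1), empirical Bayes moderation and a mean trend. The first fitted a slope on the rank of time over the 6 libraries of the doxycycline course. The second compared the 2 XEN-type lines with the 2 ESC-type lines, each line as 1 unit, and asked for a difference of at least 2. Both were two-sided with a Benjamini-Hochberg adjusted p under 0.05. Both were tested on simulated data, where all simulated genes were recovered (100%) with at most 12 false calls. The simulated slopes were 0.3 and 0.6 log2 units with a noise SD of 0.112. The simulated differences between lines were 3 and 5 log2 units with a noise SD of 0.303. This recovery holds for those noise levels only and does not show the power of either test on the real libraries. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Identifiers were matched to GENCODE M21 for gene type alone (32917 matched, 20214 protein-coding). Coordinates are 1-based in mm9.

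The 26 gene lists cover pluripotency, primed epiblast, primitive endoderm, parietal endoderm, basement membrane and collagen processing, visceral endoderm, anterior visceral and definitive endoderm, primitive streak and mesoderm, neuroectoderm, trophoblast, 2-cell-state genes, germline, fibroblast feeders, epithelial-mesenchymal genes, proliferation, p53 targets and cell-cycle inhibitors, ER stress and secretion, the FGF/ERK pathway, Wnt targets, endocytosis and lysosome, DNA methylation and Polycomb, imprinted genes, cholesterol synthesis, the SOX and GATA families, Y-linked and X-inactivation genes, and housekeeping. For each, the median difference was set against 10000 random lists matched on expression. On lists without a simulated change, 8 of 100 fell outside the central 95% of random lists.

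Named genes were Sox17, 13 fixed marker genes, the 10 largest differences in each direction, up to 4 members per list, and genes that went opposite ways in the 2 pairs of lines. Rows without a symbol and small or predicted RNAs were left out. The length part of that rule could not be applied, since the table gives no lengths. List members beyond 4, and genes in the paragraphs that say so, were chosen after their values were seen. Values of 3 genes that these rules name are not reported here. The share of the XEN difference reached was, per gene, the change from no doxycycline divided by the wild-type XEN minus ESC difference.

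Alternatives tried were pseudocounts of 0.1 and 5, a minimum of 5 FPKM or none, differences of 1 and 4 log2 units, rescaling of each library by its median ratio over 6670 genes with at least 5 FPKM everywhere, hours in place of ranks, log2 of hours, libraries left out, and Spearman correlations. Added after the data were seen were all estimates used as deposited, protein-coding genes alone, leaving out each line, the pair of lines as a block, 3 more comparisons and hours without day 6.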

Results

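Gene expression was measured in 9 libraries of mouse stem cells. Wild-type embryonic stem cells (R1 ESC) and wild-type extraembryonic endoderm stem cells (XEN, line IM8AR), a cell type of the primitive endoderm lineage, are the reference pair. The other 7 libraries come from an ESC line in which doxycycline (dox) induces the transcription factor Sox17. They are cells without dox, cells after 7, 21, 35 and 49 h and 6 days with 100 ng/ml dox, and Sox17-XEN. The Sox17-XEN label names 30 days with dox and 30 days without it, in wording that leaves the order unclear. It is read here as dox first, since the sample description holds the words dox-indep. Per the labels, ESC shared their dishes with fibroblast feeder cells and received serum and the cytokine LIF, whereas XEN cells received serum and medium that fibroblasts had conditioned. The day 6 label carries the word SORT, with no further detail. Each group has 1 library, so no value has a replicate error, and no culture without dox was collected at the later times. The absolute depth is unknown. Relative to R1 ESC it ran from 61.8% at day 6 to 127% at 7 h.

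Sox17 (ENSMUSG00000025902, chromosome 1, 4481009 to 4486494) was at 0.163 FPKM in R1 ESC and 0.909 FPKM in the Sox17 line without dox. It stood at 283 FPKM at 7 h, 281 FPKM at 21 h, 191 FPKM at 35 h, 151 FPKM at 49 h and 71.1 FPKM at day 6. Sox17-XEN, after 30 days without dox, had 101 FPKM, which is 42.2% of the 239 FPKM in wild-type XEN. A gene-level FPKM does not separate the transgene from the cells' own Sox17. The authors' lower bound is 0 in all 9 libraries, with an upper bound of 592 FPKM at 7 h.

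The comparison of wild-type XEN with R1 ESC describes the 2 states between which the Sox17 line can be placed. In XEN cells most primitive endoderm and secretory pathway genes were higher, and 22 of 31 pluripotency genes were lower. Gata4 (chromosome 14, 63817759 to 63890529) was at 337 against 0.655 FPKM, Gata6 at 99.9 against 0.214 FPKM, Sox7 at 79.4 against 0.105 FPKM and the endocytic adaptor Dab2 at 749 against 3.20 FPKM. Pou5f1 (chromosome 17, 35642982 to 35647721), the core pluripotency factor Oct4, was at 3.22 against 1080 FPKM, Nanog at 0.325 against 169 FPKM and Sox2 at 0.114 against 139 FPKM. In all, 1234 genes were higher in XEN and 980 were lower.

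By list, 22 of 31 measured pluripotency genes were lower in XEN and 0 were higher, with a median of -5.16 log2 units. Dppa5a (-9.26), Utf1 (-7.49) and Lefty1 (-7.11) were among the largest. Of 14 primitive endoderm regulators 11 were higher (median 4.94), among them Cited1 (6.69), Pdgfra (5.30), Foxa2 (4.52) and Hnf4a (3.78). Of 14 parietal endoderm markers 11 were higher (median 4.48), led by the proteoglycan core protein gene Srgn (8.81), the retinol transporter gene Stra6 (6.58) and Pth1r (6.26), and Fbln1 (-3.73) was lower. Of 18 measured genes of basement membrane and collagen processing 13 were higher, including the prolyl hydroxylase gene P4ha2 (5.86), Plod2 (5.21), Sparc (4.89) and the collagen chaperone gene Serpinh1 (4.73), while Col18a1 (-6.03) and Lox (-5.18) were lower. Of 20 visceral endoderm markers 8 were higher, such as Cubn (6.67), Rbp4 (5.03), Mttp (4.80) and Ttr (22.0 FPKM against a listed 0), while Afp was at 0.282 FPKM.

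The secretory pathway list had 13 of 20 genes higher in XEN (median 2.56), among them Sel1l (3.96), Pdia4 (3.54), Calr (3.06) and the chaperone gene Hspa5 (2.96). Of 21 endocytosis and lysosome genes 13 were higher, including Lgmn (6.00) and Clu (5.73), and Hexa (-3.16) was lower, with 10 higher after rescaling. Of 11 primed epiblast markers 5 were lower, including Otx2 (-4.41), and Fst (5.94), which the parietal list also holds, was higher. Of 18 FGF/ERK genes 7 were lower, with Fgf4 (-5.29), Fgfr1 (-4.66) and Egr1 (-3.60), and 2 were higher, including Fgfr3 (5.11). Of 11 Wnt targets 5 were lower, including the cyclin gene Ccnd1 (-5.27) and Notum (-3.95), and 1 was higher. Of the 6 genes of the 2-cell state 5 were lower, led by Zscan4d (-4.83), and 4 of 14 germline genes were lower, led by Sycp3 (-4.09).

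Of 22 fibroblast feeder markers 16 were lower in XEN (median -4.03), including Col1a1 at 0.490 against 148 FPKM. In wild-type XEN 8 of the 22 were at 1 FPKM or more. Of 20 imprinted genes 10 were lower, including Meg3 (-7.39), Rian (-6.56) and Igf2 (-3.54), and 3 were higher, including Peg3 (4.28). The Y-linked genes Eif2s3y (-5.43), Ddx3y (-3.24) and Uty (-2.53) were lower, at 0.0789, 0.00726 and 0.00596 FPKM in wild-type XEN. Sox17-XEN held them at 131, 45.9 and 16.9 FPKM, so this difference is not common to the 2 XEN-type lines. Of 18 epithelial-mesenchymal genes 6 were lower, including Cdh1 (-4.78) and Cldn4 (-5.95), and Snai1 (3.70) was higher. Of 23 proliferation genes 21 were neither higher nor lower, and the housekeeping list had a median of 0.09 (-0.36 after rescaling) with Gusb (-3.12) lower. Of 18 cholesterol synthesis genes 3, led by Insig1 (3.70), were higher (median 1.04, and 1 gene with a median of 0.59 after rescaling), 2 of 10 streak and mesoderm markers, including T (-3.50), were lower, and 2 of 5 neuroectoderm markers, including Tubb3 (-2.22), were lower (median -1.88). Of 12 trophoblast markers Tead4 (3.38) and Plac1 (2.20, and 1.93 after rescaling) were higher and Tfap2c (-4.39) was lower, with Cdx2 listed at 0 in XEN. Of 17 p53 targets and cell-cycle inhibitors 3 were lower, including Cdkn1c (-3.20), and Cdkn1b (2.33, and 1.89 after rescaling) was higher. Of 17 DNA methylation and Polycomb genes 3 were lower, including Dnmt3l (-5.86) and Cbx7 (-5.46), and 2 were higher, including Tet3 (3.44). Of 17 SOX and GATA genes 4 were higher and 4 lower, and of 15 anterior visceral and definitive endoderm markers 3 were higher, including Nepn (4.83), and 2 lower, including Trh (-7.58).

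The libraries differ in scale. The median gene stood 0.46 log2 units higher in XEN, and after rescaling 797 genes were higher and 1172 lower, so the share that is higher went from 55.7% to 40.5%. With the interval condition, Sparc and Sox7 were higher and Trh, Col5a1, Tdgf1 and Acta2 were lower. Estimates failed in XEN for Lama1, Lamb1, Lamc1, Col4a1 and Col4a2.

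**Figure D1:**
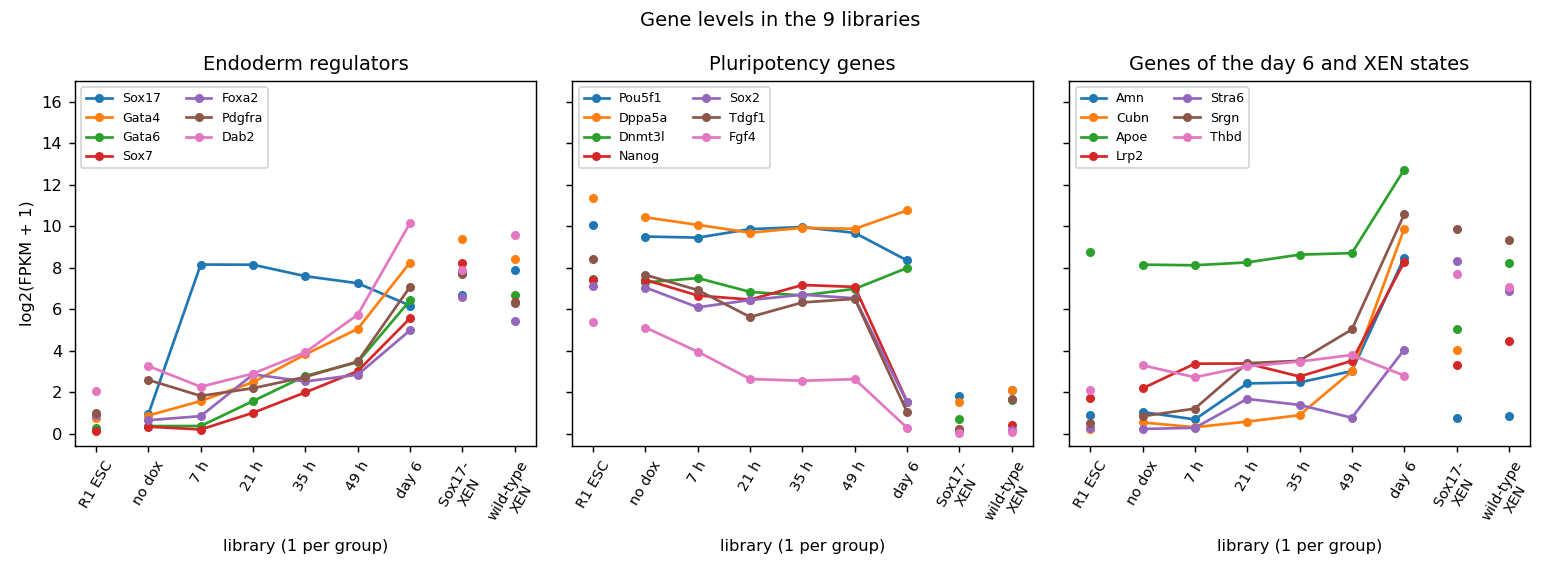
Level of named genes as log2(FPKM + 1) on the y axis in each of the 9 libraries on the x axis, with lines joining the 6 libraries of the dox course. Gata4 reached 303 FPKM at day 6, where Nanog stood at 1.89 FPKM and Dppa5a at 1733 FPKM.

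The comparison of the 2 ESC lines without dox shows how much lines differ with no induction. The pluripotency factors were at like levels, with Nanog at 169 FPKM in both, Sox2 at 131 against 139 FPKM and Pou5f1 at 723 against 1080 FPKM. Gata4, Gata6 and Sox7 were below 1 FPKM in both. The Sox17 line had 55 genes higher and 34 lower than R1 ESC, of which 12 and 2 were protein-coding. Higher were mitochondrial transcripts, mt-Rnr2 (4.28), mt-Nd5 (2.58), mt-Rnr1 (2.44) and mt-Nd2 (2.16), and Apol7d (2.60), Sod3 (2.22) and Fbn1 (2.19). Of the 22 feeder markers 2 were higher (median 1.28), with Col1a1 at 597 against 148 FPKM (1.96 log2 units after rescaling).

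At 7 h of dox the question is which genes differ first. Besides Sox17 itself (7.22), genes with large differences from no dox were the transcription factor genes Sox21 (4.33) and Nkx2-9 (4.24), the pepsinogen gene Pga5 (3.44), Sox2ot (3.16), the laminin gene Lama1 (3.06), Cyp4f14 (3.04), Col9a1 (2.93) and Igf1 (2.77). Among genes that were lower were Dynlt1f (-2.39), Postn (-2.37), Col3a1 (-2.25), Zic5 (-2.17) and Aspn (-2.14). Dynlt1f, Postn and Col3a1 were at 4.90, 56.4 and 134 FPKM without dox and at 0.125, 10.1 and 27.3 FPKM at 7 h. In R1 ESC they were at 0.228, 20.7 and 36.6 FPKM, so for these genes the no dox library stood above both others. Of 14 primitive endoderm regulators 0 were higher, and Gata4 stood at 1.96 FPKM, Gata6 at 0.285 FPKM and Sox7 at 0.143 FPKM. Of 31 pluripotency genes 0 were past the difference, with Pou5f1 at 698 FPKM and Nanog at 99.7 FPKM. The feeder list had a median of -1.11 at this time, and 2 of its 22 genes, Postn and Col3a1, were lower. Together 67 genes were higher and 51 lower, of which 19 and 4 were protein-coding, and the median gene stood -0.11 log2 units from no dox. These counts are little above the 55 and 34 genes (12 and 2 protein-coding) between the 2 ESC lines without dox. The transcript mt-Rnr2 was at 20.7 FPKM against 207 FPKM without dox, and at 20.6 FPKM at 21 h, 23.0 FPKM at 35 h and 23.9 FPKM at 49 h. In R1 ESC it was at 9.69 FPKM.

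From 21 to 49 h more primitive endoderm regulators were higher at each later time, while Pou5f1, Sox2 and Nanog stayed within the difference. Gata4 was at 4.57 FPKM at 21 h, 13.1 FPKM at 35 h and 32.0 FPKM at 49 h, and Gata6 was at 1.96, 5.86 and 9.84 FPKM. Of the 14 regulators 3 were higher at 21 h, 5 at 35 h and 8 at 49 h, when the median was 2.16 and Foxq1 (3.55), Sox7 (2.68), Dab2 (2.48) and Foxa2 (2.20) were among them. At 49 h Pou5f1 was at 817 FPKM, Nanog at 134 FPKM and Sox2 at 91.0 FPKM. Of the 31 pluripotency genes 2 were lower at 21 h, 1 at 35 h and 1 at 49 h, and Fgf4 was lower at each of these times, with -2.49 at 49 h.

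Of the 67 genes lower at 21 h 20 are protein-coding. Fgf17 (-2.82), Fgf4 (-2.48), the ERK-responsive gene Egr1 (-3.00), Zic5 (-2.64), Zic2 (-2.47), Foxd3 (-2.48) and the amino acid transporter gene Slc7a3 (-3.28) were lower at 21 h. Fgf15 was lower at 35 h (-2.91) and at 49 h (-3.21), and Pla2g1b (-3.67) and Hsd17b14 (-2.74) were lower at 49 h. Higher at 21 h were Col9a1 (5.09), Sox21 (4.79), Nkx2-9 (4.63), Igf1 (4.33), Pgam2 (3.87) and Adra2b (3.46), and at 35 h Limch1 (3.24), Phf19 (3.11) and Fam167a (2.93). At 49 h the chemokine genes Ccl20 (4.44), Cxcl5 (3.44) and Cxcl2 (3.39), Srgn (4.19), Lama1 (3.47), Col4a1 (2.55) and Cubn (2.47) were higher. Wnt targets had a median of -1.12 at 49 h, although Dkk1 (2.37), an inhibitor of Wnt signalling and the only member past the difference, was higher. Against 7 h, a comparison added after the data were seen, 49 h had 89 genes higher and 61 lower, led by Ccl20 (4.73) and Cxcl1 (4.71), while the feeder list had a median of 1.16.

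The counts at these times were small. At 21 h 112 genes were higher and 67 lower (71 and 20 protein-coding), at 35 h 92 and 69 (55 and 21 protein-coding), and at 49 h 106 and 70 (69 and 22 protein-coding). The median gene at 21 h stood -0.11 log2 units from no dox.

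A trend over the dox course was tested with limma on the rank of time in the 6 libraries. It found 0 of 14933 genes past the threshold, while 2442 genes had an upward and 1305 a downward slope at an unadjusted p under 0.05. Gata4 (1.39 log2 units per step, SE 0.17, adjusted p = 0.0801), Gata6 (1.16, SE 0.17, adjusted p = 0.0936) and Fgf15 (-0.74, SE 0.07, adjusted p = 0.0801) did not pass. These slopes are larger in size than the simulated slopes of 0.3 and 0.6, which were all recovered at a noise SD of 0.112. The count of 0 is therefore not evidence that trends are absent. With time in hours 6340 genes passed, and without day 6 that number was 1, so the result in hours rests on the day 6 library. With Sox17-XEN added as a further step 2009 genes passed. Of 17 alternatives these 3 gave a count other than 0.

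Day 6 was far from the earlier times and had a mixed profile, with most primitive and visceral endoderm markers higher and part of the pluripotency genes retained. Against no dox 771 genes were higher and 578 lower. Gata4 was at 303 FPKM, Gata6 at 84.8 FPKM, Sox7 at 46.2 FPKM and Dab2 at 1133 FPKM. The receptor genes for protein uptake Cubn (939 against 0.448 FPKM), Amn (356 against 1.05 FPKM) and Lrp2 (307 against 3.51 FPKM) were high, as were Srgn (1517 FPKM), Habp2 (120 FPKM) and Lgals2 (130 FPKM). Nanog stood at 1.89 FPKM and Sox2 at 1.84 FPKM, while Pou5f1 was at 325 FPKM and Dppa5a at 1733 FPKM.

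Of 20 visceral endoderm markers 18 were higher at day 6 (median 4.25), including the lipoprotein genes Apoe (4.58), Apom (4.65) and Mttp (5.98), and Afp (2.81), Ihh (3.97) and Soat2 (5.43). Of 14 primitive endoderm regulators 11 were higher (median 5.55), including Cited1 (6.19), Foxq1 (6.19) and Hnf4a (4.96). Of 21 endocytosis and lysosome genes 16 were higher (median 2.88), such as Lgmn (5.93), Ctsh (5.70), Ctsc (5.62) and Ctsl (5.06). Of 21 measured genes of basement membrane and collagen processing 16 were higher, led by Lama1 (7.89), Lamb1 (4.85) and Lamc1 (4.37). Estimates failed at day 6 for Col4a1 and Col4a2. Of 14 parietal endoderm markers 7 were higher, with Stra6 (3.82) and Sparc (3.66), and the intermediate filament gene Vim (-2.70) was lower. Of 15 anterior visceral and definitive endoderm markers 7 were higher, with Dkk1 (5.40), Tmprss2 (4.72) and Hhex (2.29), and 2 were lower, including Trh (-6.50).

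Of 31 pluripotency genes 14 were lower at day 6, including Tdgf1 (-6.62), Nanog (-5.88), Sox2 (-5.54) and Fgf4 (-4.84), and Tbx3 (2.49) was higher. The values for Pou5f1 (-1.15), Dppa5a (0.33) and Dnmt3l (0.70) stayed within the difference. Of 22 feeder markers 16 were lower (median -2.84), led by S100a4 (-4.82) and Acta2 (-4.78). The imprinted genes Igf2 (4.18), Meg3 (2.28) and Rian (2.14, and 1.90 after rescaling) were among 5 that were higher (3 after rescaling), and 5 were lower, with Phlda2 (-3.67) and Mest (-3.05). Among other genes, Pla2g1b, listed at 0 against 48.7 FPKM, Hsd17b14 (-5.92), Ccl2 (-5.55) and Slc7a3 (-5.48) were lower, and Ccnd1 (-4.56) and Tubb3 (-5.04) were lower too. The median gene stood 0.24 log2 units higher at day 6, and after rescaling 603 genes were higher and 684 lower, a share of 46.9% higher in place of 57.2%. With the interval condition Lama1, Lamb1, Sparc, Amn, Clic6, Klb and Foxq1 were higher and Trh and Tdgf1 lower.

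Sox17-XEN against no dox shows the state of the line 30 days after dox was withdrawn. Most primitive and parietal endoderm markers were higher, and 23 of 31 pluripotency genes were lower. Gata4 was at 660 FPKM, Sox7 at 303 FPKM, Gata6 at 210 FPKM and Foxa2 at 95.4 FPKM. Pou5f1 stood at 2.54 FPKM, Nanog at 0.163 FPKM, Sox2 at 0.129 FPKM and Dppa5a at 1.87 FPKM. In all, 862 genes were higher and 749 lower.

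Of 31 pluripotency genes 23 were lower in Sox17-XEN (median -4.73), including Utf1 (-7.94), Tdgf1 (-7.49) and Dnmt3l (-6.57), and Klf4 (2.48) was higher. Of 13 measured parietal endoderm markers 10 were higher (median 4.23), with Srgn (9.05), Stra6 (8.12), Pth1r (7.55) and Plat (5.08). Other large differences were those of the water channel gene Aqp8 (8.33), the heparan sulfate sulfotransferase gene Hs3st1 (8.20), Wfdc1 (7.60) and Myl3 (7.48). Of 19 measured genes of basement membrane and collagen processing 15 were higher, including Plod2 (5.17), Serpinh1 (5.11) and Nid1 (4.56). Visceral endoderm markers were split, with Mttp (4.75), Cubn (3.51) and Ttr (4.77 FPKM) among 8 of 20 that were higher and Apoe (-3.10) lower. Of 18 FGF/ERK genes 10 were lower (median -2.18), including the ERK-responsive genes Etv5 (-5.05), Spry4 (-2.80) and Etv4 (-2.63), while 3 were higher, including Fgfr3 (5.94) and Fgf3 (5.09). Of 20 secretory pathway genes 9 were higher (6 after rescaling), led by Creb3l1 (4.22) and Herpud1 (3.27). Of 18 cholesterol synthesis genes 4 were lower and 1, Insig1 (2.29), was higher, and after rescaling 7 were lower and 0 higher.

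The median gene stood 0.33 log2 units higher in Sox17-XEN, and after rescaling 605 genes were higher and 904 lower, a share of 40.1% higher in place of 53.5%. With the interval condition Wfdc1, Pga5, Cdh5, Ptk6, Sox7 and Serpinh1 were higher and Trh, Tdgf1 and Dppa5a lower. Estimates failed for Lama1, Lamb1, Lamc1 and Sparc in Sox17-XEN.

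**Figure D2:**
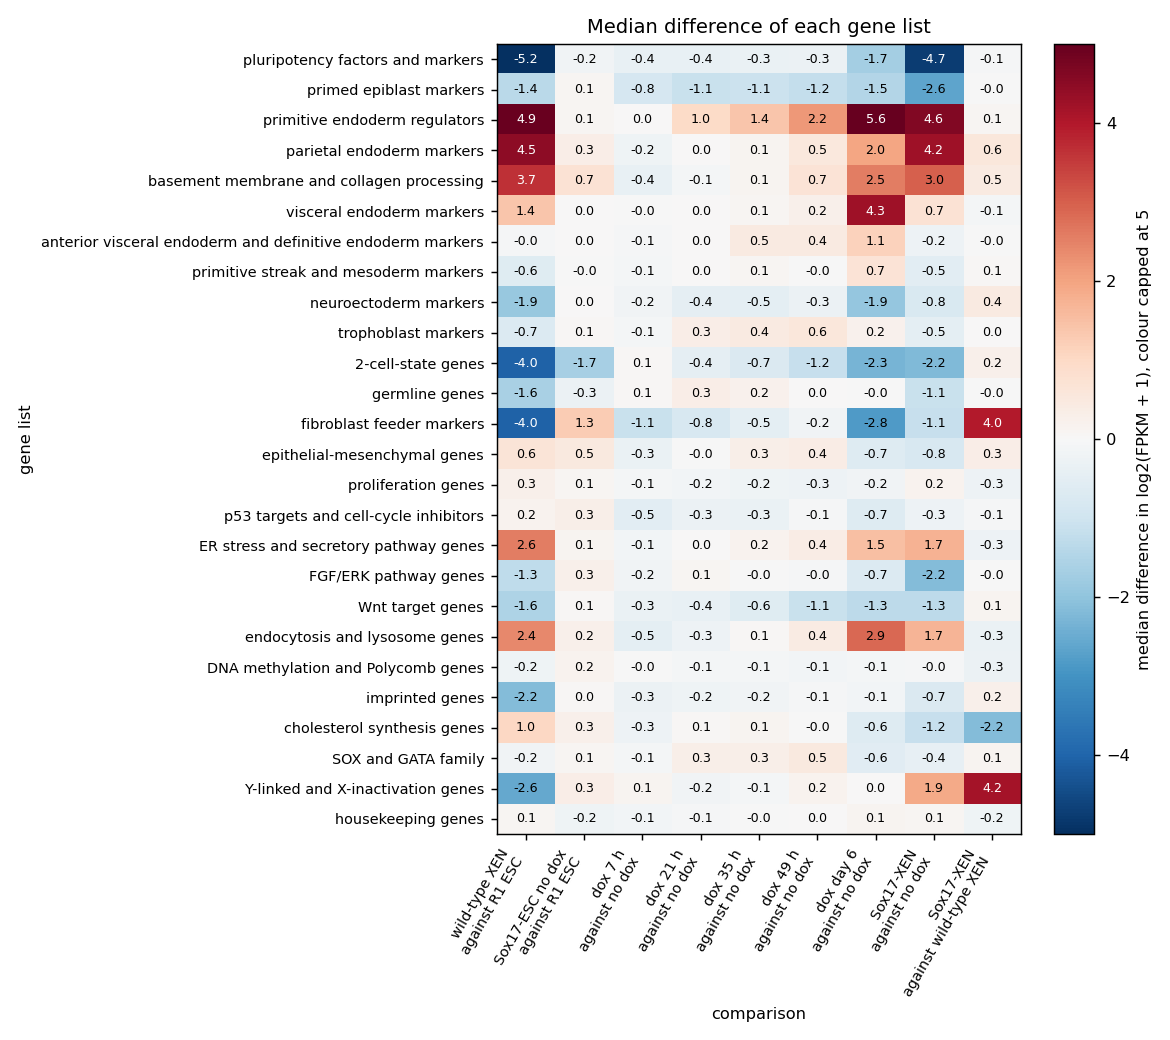
Median difference in log2(FPKM + 1) of each of the 26 gene lists on the y axis in each of the 9 planned comparisons on the x axis, with colour capped at 5. The visceral endoderm list has its highest median, 4.25, at day 6 against no dox, and the pluripotency list its lowest, -5.16, in wild-type XEN against R1 ESC.

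The wild-type pair and the Sox17 pair share no library, so their differences can be compared gene by gene. Of 14925 genes measured in both, 561 were higher and 523 lower in both pairs, and 15 were past the difference in opposite directions. If the pairs were unrelated, 70.3 and 49.1 genes would be higher and lower in both, and 118 would go opposite ways. Across genes, which are not independent replicates, Pearson's r with the wild-type difference was 0.08 at 7 h, 0.14 at 21 h, 0.21 at 35 h, 0.30 at 49 h, 0.61 at day 6 and 0.75 for Sox17-XEN. Spearman's rho was 0.06 at 7 h, 0.60 at day 6 and 0.75 for Sox17-XEN.

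The median XEN-high gene had reached -3.31% of the wild-type difference at 7 h, 1.08% at 21 h, 3.49% at 35 h, 9.73% at 49 h, 52.4% at day 6 (quartiles 24.5% and 82.7%) and 71.3% in Sox17-XEN (quartiles 46.2% and 94.3%). For ESC-high genes the medians were 6.67%, 6.43%, 7.52%, 6.62%, 55.0% and 73.8%. In Sox17-XEN 45.8% of 1226 XEN-high genes were past the difference, and at day 6 33.1% of 1227. Of 1224 XEN-high genes with a value in every library, 372 were first past it at day 6 and 274 in Sox17-XEN, and 533 passed in no library of the Sox17 line. Of 972 ESC-high genes, 338 were first past it at day 6, 233 in Sox17-XEN and 351 in none. The genes were chosen by the same wild-type difference that divides each change, so noise in that pair tends to lower the shares. No other wild-type XEN line serves as a yardstick, so shares below the full difference do not by themselves show incomplete conversion.

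**Figure D3:**
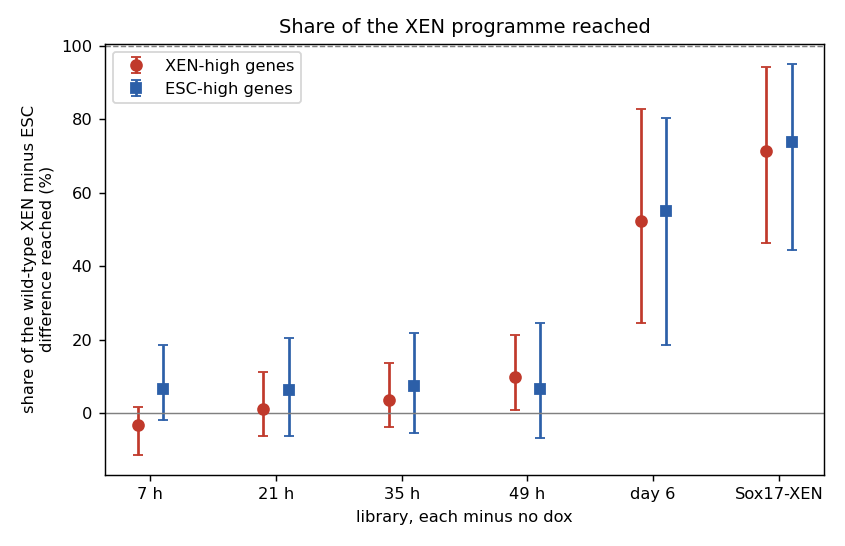
Share of the wild-type XEN minus ESC difference reached (%) on the y axis in each library of the Sox17 line on the x axis, as the median over genes with quartiles as bars. The XEN-high median goes from 9.73% at 49 h to 52.4% at day 6.

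**Figure D4:**
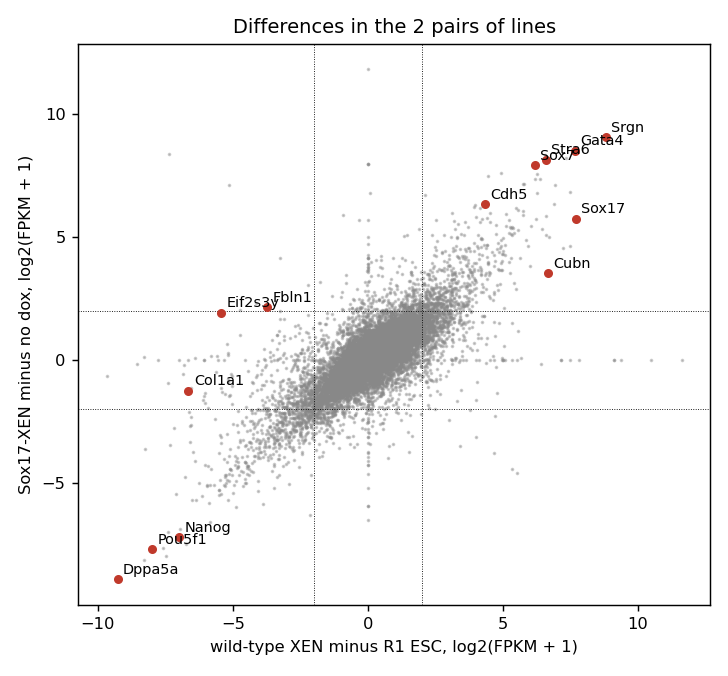
Difference of each gene in log2(FPKM + 1) in wild-type XEN minus R1 ESC (x axis) and in Sox17-XEN minus no dox (y axis), 1 point per gene with named genes marked. Pearson's r across genes is 0.75, and Fbln1 lies at -3.73 and 2.15.

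The 2 XEN-type lines were also tested against the 2 ESC-type lines with limma. Of 14925 genes 724 were higher and 581 lower in the XEN-type lines, past the threshold and a difference of at least 2. Srgn (8.93, SE 0.29, adjusted p = 0.0167), Gata4 (8.09, SE 0.39, adjusted p = 0.0171) and Sox7 (7.05, SE 0.72, adjusted p = 0.0172) were higher in 2 of 2 XEN-type lines. Dppa5a (-9.08, SE 0.42, adjusted p = 0.0171), Pou5f1 (-7.84, SE 0.28, adjusted p = 0.0167) and Nanog (-7.10, SE 0.23, adjusted p = 0.0167) were lower in both. Other genes past the threshold were Hs3st1 (7.76), Aqp8 (7.45), Stra6 (7.35), Nxf7 (7.15), Hkdc1 (7.01), Pth1r (6.91), Gata6 (6.87), Spock1 (6.76), Sox17 (6.71), Dab2 (6.05), Foxa2 (5.24), Pdgfra (5.21) and Hnf4a (4.11), and on the lower side Utf1 (-7.72), Trh (-7.61), Ifitm1 (-7.18), Tdgf1 (-7.11), Sox2 (-6.92), Lefty1 (-6.27) and Dnmt3l (-6.21). Cdx2 (-0.24) and Afp (0.54) did not pass. After rescaling 464 genes were higher and 733 lower. The spread is that between lines, and limma found 0 genes without R1 ESC (560 higher and 603 lower at an unadjusted p under 0.05) and 0 without the Sox17 line lacking dox (872 and 622), where the lone ESC line is assumed to vary like the XEN-type lines.

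Sox17-XEN against wild-type XEN shows how the converted line differs from a XEN line. Of 14 primitive endoderm regulators 12 were neither higher nor lower, and Cited1 (-2.17) and Grb10 (-3.59) were lower. Gata4 was at 660 against 337 FPKM, Gata6 at 210 against 99.9 FPKM, Sox7 at 303 against 79.4 FPKM and Pdgfra at 207 against 78.3 FPKM. Dab2 was at 232 against 749 FPKM and Sox17 at 101 against 239 FPKM. Of 32 pluripotency genes 0 were past the difference. In all, 409 genes were higher and 238 lower in Sox17-XEN.

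Of 22 feeder markers 17 were higher in Sox17-XEN (median 3.98), with Col1a1 at 252 against 0.490 FPKM, Col1a2 at 184 against 0.511 FPKM and Col3a1 at 90.7 against 0.116 FPKM, beside Fbln1 (6.19) and Lox (5.89). Of 18 cholesterol synthesis genes 9 were lower (median -2.16), including Sc4mol (-3.26), Sqle (-2.92) and Fdps (-2.80). Of 20 visceral endoderm markers 5 were lower, Spink3 (-4.98), Apoe (-3.17), Rbp4 (-2.88), Cubn (-2.86) and Cited1 (-2.17), and the keratin gene Krt19 (-4.43) and Cldn6 (-3.21) were lower too. The transcription factor gene Creb3l1 (4.79), the p53 target Pmaip1 (4.61), Egr1 (4.38), the Wnt target Axin2 (2.72) and Fgf3 (2.82) were higher, and Dusp4 (-2.57) and Dusp6 (-2.51) were lower. Imprinted Meg3 (5.87), Igf2 (4.03) and Rian (3.45) were among 5 of 20 that were higher, and Grb10 (-3.59) was lower. All 5 genes of the Y-linked and X-inactivation list were higher, including Eif2s3y (6.94), Ddx3y (5.54) and Xist (2.19). Wild-type XEN had at most 0.0789 FPKM of each Y-linked gene on that list. Outside the lists, Ftl2 (7.57), the acyltransferase gene Mogat1 (6.65) and Ptn (66.8 FPKM against a listed 0) were higher, and Cdh6 (-4.26), Wnt11 (-4.00) and the glutamate transporter gene Slc1a3 (-3.99) were lower. Col5a1 and Ddx3y were higher with the interval condition.

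Day 6 was set against each XEN line in comparisons added after the data were seen. Against wild-type XEN 616 genes were higher and 326 lower, and against Sox17-XEN 543 were higher and 444 lower. Of 20 visceral endoderm markers 11 were higher against wild-type XEN and 13 against Sox17-XEN, with Amn (7.61 and 7.73). Of 31 pluripotency genes 11 were higher in each, with Dppa5a (8.67 and 9.24) and Pou5f1 (6.27 and 6.52). Apoc1 (7.61 and 7.82) and Fmr1nb (6.81 and 6.65) were higher in both as well. Of the parietal endoderm markers 6 of 14 were lower and 1 higher against wild-type XEN, and 5 of 13 lower against Sox17-XEN, with Fst (-6.40 and -5.56), and Wfdc1 (-4.61 and -7.19) was lower too.

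**Figure D5:**
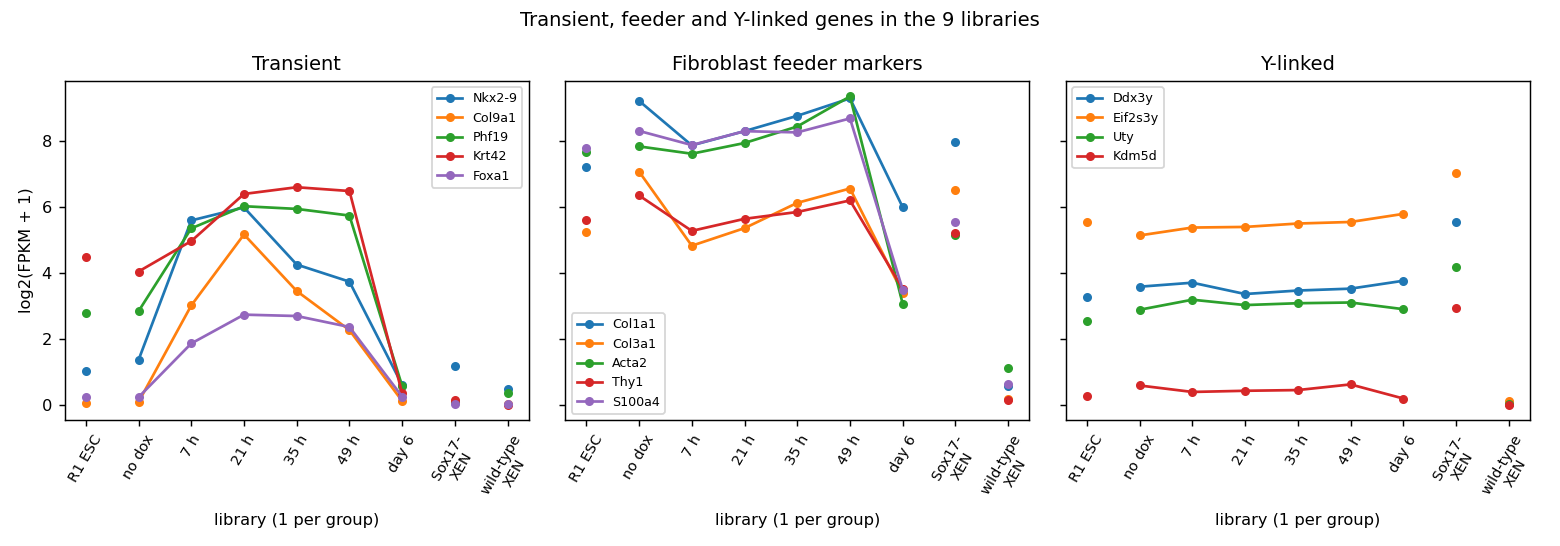
Level of transient, fibroblast feeder and Y-linked genes as log2(FPKM + 1) on the y axis in each of the 9 libraries on the x axis, with lines joining the dox course. Nkx2-9 reached 62.4 FPKM at 21 h, Col1a1 was at 62.7 FPKM at day 6 and 0.490 FPKM in wild-type XEN, and Ddx3y was at 45.9 FPKM in Sox17-XEN.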

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

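Comparing the 2 pairs of lines for opposite differences was planned, but doing so without the interval condition was chosen after the data were seen, and no explanation was tested. The wild-type pair is XEN against R1 ESC and the Sox17 pair is Sox17-XEN against no dox. In 15 of 14925 genes both pairs were past 2 log2 units with opposite signs, against 118 for independent lists of the same sizes. Since the 2 ESC lines have like levels, opposite calls are limited by construction, and this contrast decides nothing. The difference between the pairs was not tested, since each value comes from 1 library. Of the 15 genes all but 3 are small RNAs or genes with only a clone or predicted-gene name.

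The matrix protein gene Fbln1, on the parietal endoderm list, was lower in the wild-type pair (-3.73) and higher in the Sox17 pair (2.15), which differ by -5.88. It was at 17.8 FPKM in R1 ESC, 22.5 FPKM without dox, 103 FPKM in Sox17-XEN and 0.421 FPKM in wild-type XEN. After rescaling its difference in the Sox17 pair is 1.82, which is not past 2 log2 units. The ribosomal pseudogenes Rps24-ps3 (3.78 and -2.03) and Rps2-ps13 (2.99 and -2.45) differ between the pairs by 5.81 and 5.44. In wild-type XEN they were at 93.9 and 218 FPKM, and in Sox17-XEN at 1.92 and 5.40 FPKM. Reads shared with their parent genes were not examined.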

How the results depend on the processing

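Leaving out lines, the pairs as a block, protein-coding genes alone, estimates as deposited, hours without day 6, reordered libraries and all further settings run without the interval condition were chosen after the data were seen. None of the fixed genes, largest differences and list members past the difference reversed in the planned comparisons with other pseudocounts or rescaling. That outcome was fixed in advance and is no sign of robustness. A pseudocount cannot change the sign of a difference, and the median shifts were at most 0.46 log2 units in size, well under 2. Rescaling turned the balance of higher and lower genes from 1234 and 980 to 797 and 1172 for wild-type XEN against R1 ESC, from 771 and 578 to 603 and 684 at day 6, from 862 and 749 to 605 and 904 for Sox17-XEN against no dox, and from 724 and 581 to 464 and 733 for the types of lines. It also changed the sign of list medians near 0, such as that of proliferation genes in wild-type XEN against R1 ESC (0.27 to -0.18). The absolute depth is unknown, which leaves small differences of weak genes open. The cause of each change below was not tested, except that a smaller required difference, or fewer genes compared, alters a count by construction.

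Without the interval condition the counts were 2214 genes for wild-type XEN against R1 ESC, 89 for no dox against R1 ESC, 118 at 7 h, 179 at 21 h, 161 at 35 h, 176 at 49 h, 1349 at day 6, 1611 for Sox17-XEN against no dox and 647 for Sox17-XEN against wild-type XEN. With it they were 6, 0, 0, 0, 0, 0, 9, 9 and 2. In the same order, without the interval condition, a pseudocount of 0.1 gave 4184, 223, 230, 426, 390, 456, 2669, 3143 and 1573 genes, and a pseudocount of 5 gave 895, 34, 41, 46, 46, 54, 566, 634 and 242. A difference of 1 log2 unit gave 6238, 804, 455, 762, 693, 832, 4549, 5272 and 2373. Protein-coding genes alone gave 14 for no dox against R1 ESC, 23 at 7 h, 91 at 21 h, 76 at 35 h and 91 at 49 h. The other 40 of 72 such counts, under rescaling, other minimum levels, estimates as deposited and, in 4 comparisons, protein-coding genes alone, stayed within 1.5 times the main count.

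The limma trend on rank gave 0 genes (2442 rising and 1305 falling at an unadjusted p under 0.05). Beside it, time in hours gave 6340 genes, hours without day 6 gave 1 and Sox17-XEN as a last step gave 2009, and the other 14 of 17 alternatives gave 0. In hours, 17 of 99 other orders of the libraries kept day 6 last, and these gave 3933 to 5986 genes, while orders with day 6 elsewhere gave at most 1. For the 2 types of lines (1305 genes), a pseudocount of 0.1 gave 2177 and a pseudocount of 5 gave 535. With each line left out in turn the count ran from 0 to 1473, and it was 0 without R1 ESC (limma, 560 higher and 603 lower unadjusted) and 0 without the no dox library (872 and 622). The remaining 7 of 11 alternatives stayed within 1.5 times, among them the fit with the 2 pairs of lines as a block (1214 genes, 1148 of them in both fits, on 1 residual degree of freedom). Only the Sox17 pair shares a parent line.

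All 72 alternative shares of the XEN difference and 24 correlations stayed close to their main values. The 9 rescaled Sox17 levels stayed within the authors' intervals, but these start at 0 and are wide, so that check could hardly fail. On rescaling Sox17 went from 239 to 190 FPKM in wild-type XEN, from 101 to 84.9 FPKM in Sox17-XEN and from 283 to 324 FPKM at 7 h. Of 702 list medians 654 stayed and 48 moved, nearly all of them (47) with a pseudocount of 0.1. Of 2346 values for these genes 2068 kept their side of the difference, 233 fell below it with a pseudocount of 5, 37 of list members fell below it on rescaling (such as Cdkn1b and Plac1 in wild-type XEN against R1 ESC and Insig1 in Sox17-XEN against no dox), and 8 went past it with a pseudocount of 0.1.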

Other observations

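Of the tests below, that of rescaling at day 6 and that of chromosome dosage were set before their results were seen, and the others after. Some genes were higher on dox up to 49 h and not at day 6. Of 41 genes past 2 log2 units over no dox at 21, 35 and 49 h, 15 were within 1 log2 unit of no dox or below it at day 6 and in both XEN lines, a rule chosen after the values were seen. Of the 41 genes 21 were also past the difference at day 6 and 13 in wild-type XEN over R1 ESC. Among the 15 the homeobox gene Nkx2-9 was at 1.56 FPKM without dox, 47.2 FPKM at 7 h, 62.4 FPKM at 21 h and 0.511 FPKM at day 6. Col9a1 was at 34.9 FPKM at 21 h and 0.0767 FPKM at day 6, and the Polycomb-associated gene Phf19 at 64.1 and 0.470 FPKM. The keratin gene Krt42 was at 96.1 FPKM at 35 h and 0.265 FPKM at day 6, and the forkhead gene Foxa1 at 5.45 FPKM at 35 h and 0.181 FPKM at day 6. Fam167a, Sox2ot, Ism2, Susd1, Cited4, Id4, Slc32a1 and Slc6a17 are also among the 15.

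At day 6 133 genes were at least 2 log2 units above no dox, R1 ESC and both XEN lines. Besides Amn and Apoe they include the carbonic anhydrase gene Car4 (652 FPKM, against 1.30 FPKM in Sox17-XEN and 23.7 FPKM in wild-type XEN), the glypican gene Gpc3 (920 FPKM), Ggt1 (93.6 FPKM), Myo7a (63.5 FPKM), Cd82 (52.5 FPKM), Plbd1 (57.4 FPKM) and the homeobox gene Hesx1 (17.7 FPKM). They also include the mitochondrial ribosomal RNA mt-Rnr1 (455 FPKM, against 96.2 FPKM without dox and 16.9 FPKM in R1 ESC) and Lars2 (139 FPKM, against 25.7 FPKM without dox), and whether ribosomal RNA carry-over differs at day 6 was not tested. Igf2 was at 170 FPKM at day 6 and 0.0279 FPKM in wild-type XEN.

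Day 6 combined pluripotency transcripts with visceral endoderm genes above both XEN lines. A mixture of unconverted cells and cells like either XEN line cannot exceed its parts, yet 133 genes did, the observation that prompted the test. Counted the same way, there were 15 for R1 ESC and 45 for 49 h. The R1 ESC count could not exceed 34, the number of genes lower without dox than in R1 ESC. It is thus small by construction, and its contrast with 133 decides nothing. Unconverted cells like those without dox would also keep pluripotency genes at a common share of no dox. Over 19 such genes the interquartile range was 4.53 log2 units, with values from 0.521% for Tdgf1 to 163% for Dnmt3l. At 49 h the same genes already ran from 15.3% for Fgf4 to 223% for Dppa3, so unconverted cells on dox need not hold a common share. The spread therefore does not exclude such cells as a part of the day 6 library. Rescaling left 90.2% of the 133 genes past the difference, just over the 90% bound set for it, which argues against scaling as the whole cause. Of those genes 7.52% were already past it at 49 h, but time, dox, medium and the sort named in the day 6 label cannot be told apart, and a stage of conversion stays open as well, untested.

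Fibroblast markers were present in the Sox17 line and nearly absent from wild-type XEN, with Col1a1 at 597 FPKM without dox, 62.7 FPKM at day 6 and 252 FPKM in Sox17-XEN. RNA from feeder cells of fixed composition would keep the 14 tested markers in a common ratio, and the SD of log2(day 6 / no dox) was 0.852 against 0.290 at the 95th percentile of matched random genes at 35 and 49 h, but that reference is close to technical noise and decides nothing. The median difference between Sox17-XEN and wild-type XEN was 3.98, and 3.96 after rescaling. The median shift between these 2 libraries was only -0.08 log2 units, so the outcome of rescaling was fixed by it. A shift of that size is too small to account for the difference, which argues against scaling. Their estimated depths were at a ratio of 94.0%, which argues against depth as far as the estimate goes. Of the 22 list genes 8 reached 1 FPKM in wild-type XEN and 1 is on another list. RNA from feeder cells, removal of such cells by the sort at day 6, and expression by the Sox17 line itself may each contribute, and no biological explanation was tested.

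Y-linked genes stood higher in Sox17-XEN than in the other 8 libraries, with Eif2s3y at 131 FPKM against 34.2 FPKM without dox and Ddx3y at 45.9 FPKM, 4.19 times its no dox level. The smallest of the 4 differences from no dox after rescaling, that of Uty, was 0.98, under the bound of 1 set for scaling as a cause. By that bound scaling is not excluded for the 4 genes as a set. The median shift between the libraries was 0.33, smaller than each unscaled difference (1.29 to 2.36). A shift of that size covers only part of these differences. For Ddx3y, Eif2s3y and Kdm5d, split off after the Uty value was seen, the smallest was 1.58. That split left out only the gene under the bound, so its outcome was fixed and it decides nothing. The test for a different dosage of whole chromosomes met its bound, with the median of chromosome 12 0.42 higher. Of 20 chromosomes 2 lay outside the central 99% of random gene sets, and 1 of them was also beyond 0.3 log2 units. In the wild-type pair, which holds no Sox17 line, chromosome 12 was 0.43, chromosome 16 0.70 and chromosome 19 0.42 higher. Shifts of this size therefore arise without the Sox17 line, and the test does not decide on dosage. No test measured the Y chromosome itself or any biological explanation.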
